A study of Homo sapiens with 24 samples.

How the data were processed

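Ago2 CLIP, RNA-seq and LO band CLIP libraries were made from untreated and arsenite-treated 293S cells, with 4 biological replicates in each of 6 groups, and per the labels the CLIP and RNA-seq libraries of a replicate came from the same cells. The submitters' processing notes name Bowtie 0.12.8, TopHat, DESeq and the genome build hg19, without giving a role or order. The peak caller, its filters and the step that normalized the CLIP values are not given in the sources used here. The 2 deposited tables hold 1 value per feature for all replicates together, and 0 columns hold values of single samples.

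The peak table gives each peak's position, annotated transcript and region, the matches to 7-nucleotide seeds of 50 miRNA families, and a log average and a log ratio of normalized CLIP abundance, per the file headers. The log base and the normalizer of these values are not stated. The ratios may therefore be relative to RNA abundance or to library size, and they were used as they are, without conversion to folds. The log averages ran from -11.87 to 4.01 and the log ratios from -3.16 to 5.03. Coordinates are printed as deposited, on hg19, and whether starts count from 0 or 1 is not stated. Peak length was taken as end minus start plus 1, with a median of 50 nucleotides and a range of 3 to 219. Of the peaks, 3675 overlap the previous peak on their strand.

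The miRNA table uses miRBase 18 names, per the file headers. Its means are signal values, that is read counts divided by size factors and averaged by the authors for each treatment. The authors also deposited the ratio (fold) of the 2 means and its log2 value. The p-values and adjusted p-values in it are the authors' deposited DESeq results, and whether that model used the pairing of replicates is not stated. Of the 1213 entries 1000 are mature miRNAs and 213 are other parts of hairpins, which held 0.0399% of the summed means. A mean of 0 in 1 treatment occurred in 130 entries.

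The tests planned before the data were examined (edgeR or limma on replicates, camera on gene lists, the CLIP to RNA interaction, and permutations over pairs) could not be run, since no replicate values were in the tables used. In their place, the median of a group of peaks, genes or miRNAs was compared with 10000 random groups of the same size matched on 10 equal bins of the log average or mean, and a group is called outside when its median lies beyond the central 95% of the random medians. This replacement was chosen after the tables had been seen, although the regions, the gene and miRNA lists and the sites of 21 families were fixed beforehand. The other families were taken from the table, and the small nucleolar RNA, host gene, lincRNA model, long RNA and secretory groups were formed after the data had been examined. It describes these tables and carries no p-value. The random groups treat peaks as independent, so their ranges are too narrow for groups with several peaks per gene. Matching on 5 equal bins of peak length and on region, the comparison within gene and region (labels shuffled 10000 times), and all relations other than that of miRNA fold change with peak medians over all families or those over 1% were added after the data had been examined.

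For gene lists, the peak with the highest log average stood for each gene, and lists with at least 5 measured genes were described. miRNA lists needed at least 2 members with a mean of at least 20. A miRNA named without its arm was taken as the arm with the higher mean, which for miR-106b was the 3p arm. Families were named by their most abundant member or their usual name, and their fold change came from the summed means of their members. Correlations over families with at least 20 peaks used 100000 permutations, two-sided, with Benjamini-Hochberg adjustment over all 17 relations computed.

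Named peaks were the 12 highest and 12 lowest log ratios, 1 per gene, among peaks in the upper 75% of log averages, the 5 peaks with the highest log average, AGO2, and up to 4 members of each list. The planned rule also asked for an adjusted p and the same direction in all pairs, which the table does not give. Members of lists were to be taken by the smallest p and were taken by the largest absolute log ratio instead. DGCR8, CDKN1A, HSPH1, ATF4 and G3BP1 fall outside the rule and were named after their values were seen. Named miRNAs were the 10 with the highest mean, and none passed the adjusted threshold of 0.05 for the other part of the rule.

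On simulated data drawn from the 6088 genes, lists with no shift lay outside the range in 2% (20 genes) and 6% (50 genes) of 100 lists. A shift of 0.5 was found in 38% of lists of 20 genes and 66% of lists of 50, and a shift of 1 in 86% and 100%. A simulated correlation of 0 over 49 families passed the threshold in 3% of 100 draws and one of 0.6 in 100%. Only the log averages were real in these simulations. The log ratios and family values were independent draws, and 400 random groups were used per list. Real lists hold related genes and real families share peaks, so these rates need not hold for them. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. Wilson intervals cover counting of peaks only. Sequencing depth is unknown. Alternatives tried were a filter on low log averages, all peaks or the median peak of a gene, non-overlapping peaks, longer peaks, leaving out 4 long noncoding RNAs, and other thresholds and pseudocounts for miRNAs.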

Results

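The study compared 293S cells, a line derived from human embryonic kidney, with and without sodium arsenite. Arsenite is a thiol-reactive compound that blocks translation initiation and induces stress granules. Treated cells received arsenite at 1 mM during 30 min. Ago2, the Argonaute protein that carries miRNAs to their target RNAs, was crosslinked to RNA and immunoprecipitated (CLIP), and total RNA of the same cells was sequenced. A separate set of libraries, called the LO band in the labels, gave the abundance of the miRNAs bound to Ago2. The 24 samples formed 6 groups of 4 biological replicates, namely mRNA CLIP, RNA-seq and LO band CLIP, each untreated and with arsenite. The files used here held 1 value per peak or per miRNA over all replicates, so no standard deviation, replicate test or sequencing depth could be given. RNA-seq values were not analysed here.

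The first comparison asked how the Ago2 signal on mRNAs and noncoding RNAs differed between arsenite-treated and untreated cells. The authors' deposited table listed 24041 peaks in 6088 genes, each with a log average and a log ratio of arsenite over untreated signal. These peak values are the authors', their log base and their normalizer are not stated, and they were therefore not turned into folds. Most peaks had more normalized signal with arsenite: 70.3% of log ratios lay above 0 (Wilson 95% interval over peaks 69.7 to 70.9%), with a median of 0.65 and quartiles of -0.16 and 1.49. With the peak of the highest average taken for each gene, 79.9% lay above 0 and the median was 1.10. Because the log ratios were not centred, the zero point depends on the authors' scaling, and the comparisons below set groups of peaks against each other. Peaks overlap and cluster in genes, so the intervals over peaks are too narrow.

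The position of a peak in the transcript went with its log ratio. Peaks in 3' untranslated regions (3'UTRs), where most known miRNA sites lie, had the highest median, 0.88 over 12251 peaks, and 76.2% of them were above 0. Coding sequence (CDS) peaks had a median of 0.58 over 8303 peaks, and 5'UTR peaks a median of 0.25 over 2169 peaks. The 1318 peaks in exons of noncoding RNAs had a median of -0.18, and only 42.6% of these lay above 0. Against 10000 random peak sets of the same size and the same log averages, the 3'UTR median was higher by 0.21, and the differences were -0.068 for CDS, -0.41 for 5'UTRs and -0.74 for noncoding exons. The random sets were drawn from all peaks, those of the region included, and 3'UTRs held 51.0% of all peaks but noncoding exons 5.48%. The sizes of these differences therefore cannot be compared between regions. Each of the 4 region medians lay outside the central 95% of the random medians. With 1 peak per gene they did so too, with differences of -0.11 for CDS, -0.84 for 5'UTRs and -0.35 for noncoding exons, where the median itself was 0.67 over 303 genes. Without XIST, MALAT1, KCNQ1OT1 and NEAT1 the median of the other 783 noncoding peaks was 0.19 and the difference -0.45. That is a description of this table and not a test across replicates.

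Peaks with a 7-nucleotide seed match to any of the 50 miRNA families listed by the authors had higher log ratios than peaks with none. The 7581 peaks with a match had a median of 1.06, and 79.2% lay above 0. The 16460 peaks with no match had a median of 0.48, and 66.2% lay above 0. Medians were 0.99 for peaks matching 1 family, 1.29 for 2 families and 1.34 for 3 or more. Matched random sets lay 0.40 below the peaks with a match, and 0.34 below them when length and region were matched as well. These sets were drawn from all peaks, 31.5% of which had a match, so they understate the difference from peaks with none. The difference from matched sets was 0.33 within 3'UTRs, 0.38 within CDS and 0.13 within 5'UTRs, all outside the random range. Within noncoding exons it was 0.10, inside that range, and 0.12, outside it, when length was matched too. When peaks with and without a match were compared within the same gene and region, the median difference over 2654 such pairs was 0.25, against a range of -0.03 to 0.03 with shuffled matches. The pairs within 3'UTRs had a median difference of 0.31 and those within CDS 0.25, both outside the shuffled range. Without regard to gene, medians with and without a match lay farther apart, at 1.20 and 0.68 in 3'UTRs and 0.96 and 0.45 in CDS. In 5'UTRs the median difference was -0.01 over 154 pairs and in noncoding exons 0.21 over 69 pairs, both inside the shuffled range.

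**Figure D1:**
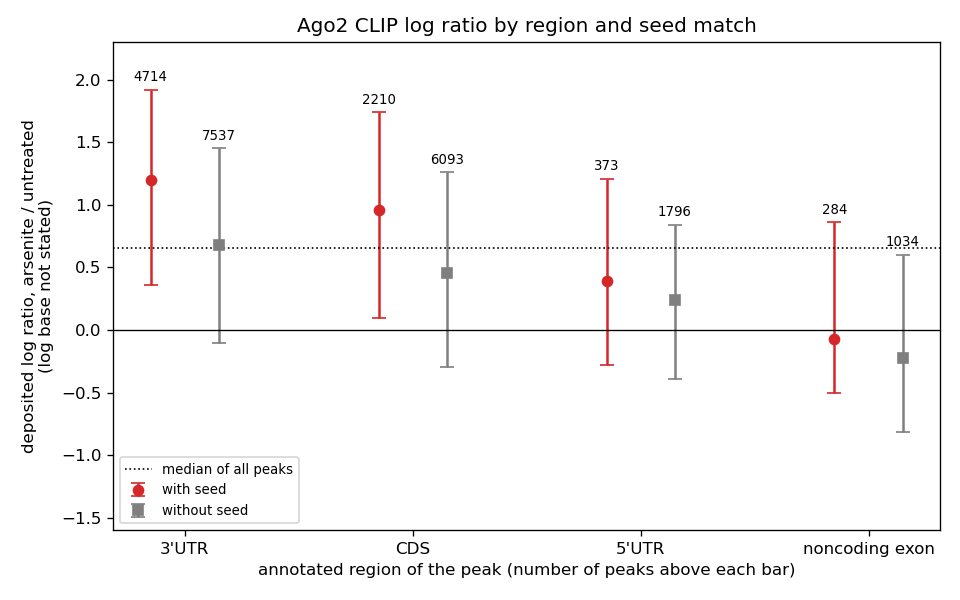
Median deposited log ratio of arsenite over untreated Ago2 CLIP signal (vertical axis, log base not stated) for peaks with and without a seed match in each annotated region, where bars span the quartiles over peaks and numbers above them count the peaks. Medians with a match lay above those without in each region, from 1.20 against 0.68 in 3'UTRs to -0.07 against -0.22 in noncoding exons, the last difference being inside the random range unless length was matched.

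The seed families differed widely. Peaks matching the miR-25/92 family had a median log ratio of 1.72 over 430 peaks, and 95.3% of them lay above 0. The miR-17 family followed with 1.67 over 716 peaks, the miR-30 family with 1.60 over 335, miR-151a-3p with 1.58 over only 21 and the miR-19 family with 1.57 over 556. Peaks matching let-7 had a median of 1.42 over 350 peaks, and the 994 peaks matching miR-15/16 a median of 0.92. At the other end, peaks matching miR-18a-3p had a median of 0.05 over 162 peaks, those of the miR-34 and miR-449 family 0.18 over 168, those of miR-210 0.20 over only 25 (inside the random range), those of the miR-28-5p and miR-708 family 0.21 over 162 and those of miR-324-3p 0.22 over 277. Of the 50 families, 22 had a higher and 6 a lower median than matched random sets, where 2.5 outside the range would be met by chance. These sets were drawn from all peaks, most of which match no family, and peaks with any match lay 0.40 above such sets. The 22 higher medians therefore partly restate the difference between peaks with and without a match. They do not show by themselves that families differ. With length and region matched too, 22 were higher and 5 lower, and with 1 peak per gene 14 were higher. The medians of all 50 families lay above 0.

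**Figure D2:**
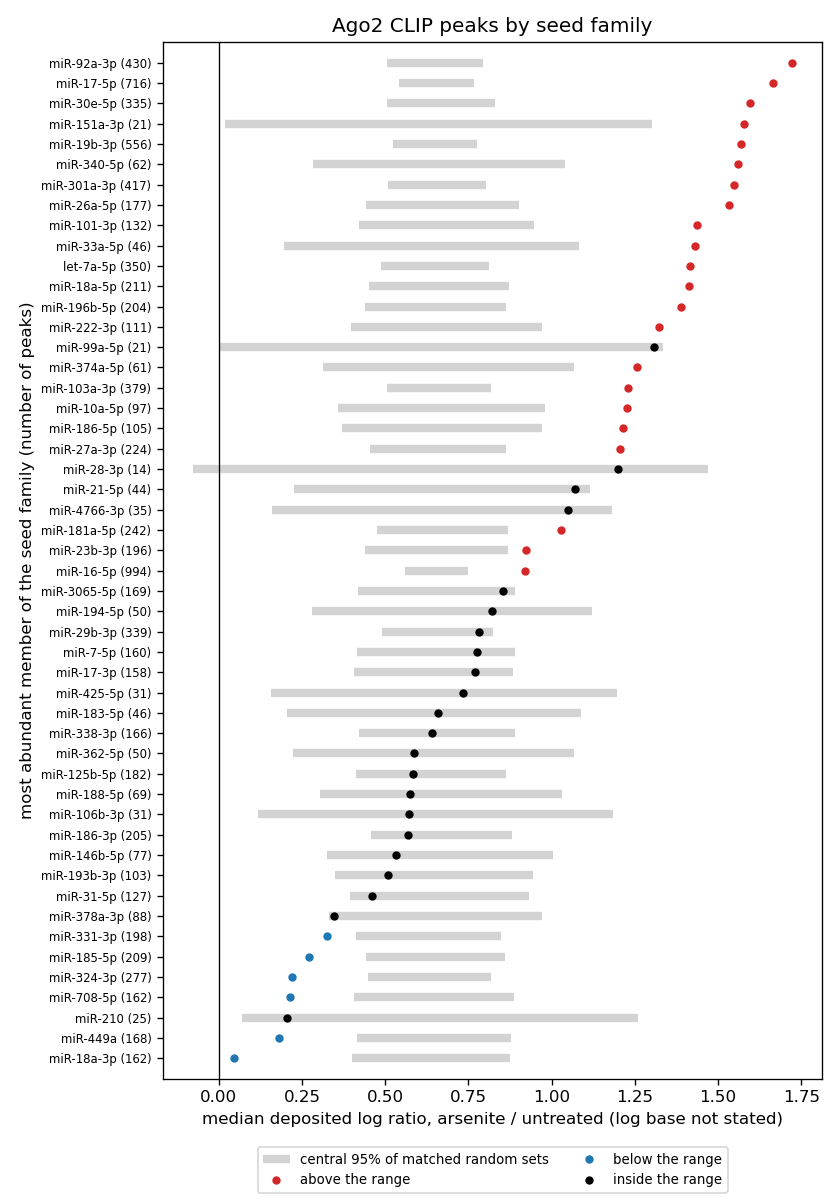
Median deposited log ratio of arsenite over untreated Ago2 CLIP signal (horizontal axis, log base not stated) for the peaks matching each of 50 seed families, with gray bars for the central 95% of 10000 random sets matched on log average. Red points (22 families) lie above their range, blue points (6 families) below it and black points inside it. The random sets were drawn from all peaks, with or without a seed match.

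The largest log ratios came from a mixed set of genes. Among peaks in the upper 75% of log averages, the authors' deposited table gave 5.03 for a CDS peak in DEGS1, a ceramide desaturase (build hg19, chromosome 1, 224377463 to 224377506), and 5.02 for a CDS peak in TXNDC17, a thioredoxin-like protein. EIF2AK3, which encodes the endoplasmic reticulum stress kinase PERK, had 4.45 at a CDS peak that matches the miR-17 seed (chromosome 2, 88913327 to 88913364). The histone genes HIST1H1D and HIST1H3A had 4.67 and 4.32. RPN2, a subunit of the oligosaccharyltransferase, had 4.37 in its 3'UTR (chromosome 20, 35869713 to 35869755), and CALU, a calcium-binding protein of the secretory pathway, 4.34. CHCHD10, a mitochondrial protein, had 4.36, HSD17B12, a fatty acid elongation enzyme, 4.07, and the small nucleolar RNA SNORA67 4.14. LINC00324 had 4.50 and the lincRNA model TCONS_00003049 had 4.40. Some of these peaks stood well above the rest of their gene. The median over all peaks was 2.40 for DEGS1 (13 peaks), 2.22 for HIST1H1D (3), 1.84 for CHCHD10 (5) and 1.68 for CALU (6). It stayed high in others, such as RPN2 with 3.47 over 12 peaks, and TXNDC17 had 1 peak only. Of these 12 peaks, 5 matched a listed seed family and 7 matched none, where 68.5% of all peaks matched none.

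Of the 12 lowest log ratios, 11 were at peaks with no seed match, where 68.5% of all peaks had none. The authors' deposited table gave -3.16 for the lincRNA model TCONS_00002573 and -3.08 for HOXA6, a homeobox transcription factor (chromosome 7, 27187279 to 27187344). NAT8L, the enzyme that makes N-acetylaspartate, had -3.07 at 1 of its 44 peaks, and the median of all its peaks was -0.98. Values between -3.04 and -2.79 were listed for FLJ45340, RBM14, SLC2A8, C17orf70, SH2B1, PKD1P1, NACC2, NKX3-2 and CHKB. RBM14 and NACC2 had medians of -0.09 and -0.02 over their 24 and 26 peaks, so a single low peak did not stand for the whole transcript. The 5 peaks of the highest log average lay in SNORA74A, ARHGAP4, SNORA33, LINC00116 and LOC284801, with log ratios of 1.87, -0.22, 2.44, 3.11 and 0.30 in the authors' deposited table. AGO2 itself, named EIF2C2 in the table, carried 7 peaks with a median log ratio of 1.44, from -0.64 to 2.21, and the highest was a CDS peak with a miR-17 match.

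Gene lists fixed before the data were examined showed which groups stood apart. With 1 peak per gene, 10 of the 12 lists had at least 5 measured genes, and 2 of the 10 lay outside the range of matched random lists, where 0.5 would by chance. Over all genes 79.9% of such peaks lay above 0, so the counts above 0 given for lists are to be read against that share. The list of histone mRNAs, most of which lack a poly(A) tail and are made in S phase, was high: all 44 measured genes, among them SLBP, which encodes the protein that binds these mRNAs, had log ratios above 0, with a median of 1.54 (percentile 98.95 of matched lists). HIST1H3I had 3.87 and HIST1H2BO 3.22 in the authors' deposited table. With the median over each gene's peaks the list reached only percentile 96, inside the range. Textbook targets of miR-17-92, let-7 and miR-15/16 had a median of 1.62, with 35 of 38 genes above 0 (percentile 98.75). STAT3 had 3.98, BTG3, an antiproliferative protein, 2.60, and CDK6, a cell cycle kinase, 2.27, whereas CDKN1A, a cell cycle inhibitor, had -0.13 in the authors' deposited table. The median over all peaks was 0.50 for CDKN1A (13 peaks) and 1.08 for CDK6 (14 peaks), so both of their values are those of 1 peak. For STAT3 it was 2.84 over 2 peaks and for BTG3 2.60 over 7. The textbook target list lay at percentile 78.24 when all peaks of its genes were used, so it stood apart only at the peak of the highest average. The random lists were matched on log average and not on seed matches, which 44.6% of all genes had at that peak. Whether the target list only restates the seed difference was not tested.

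Translation and miRNA pathway lists lay inside the range with 1 peak per gene. Ribosomal protein and translation factor mRNAs, which share a terminal oligopyrimidine start, had a median of 1.38, with 62 of 66 genes above 0 (percentile 95.77). RPL17 had 3.41 and RPS10 3.27 in the authors' deposited table. The microRNA machinery list had a median of 1.56, with 22 of 25 genes above 0 (percentile 92.27, and 76.075 with the median over each gene's peaks). Among its members, DICER1, the miRNA-processing RNase, had 2.41 and CNOT1, the deadenylase scaffold, 2.62, while DGCR8, a partner of Drosha whose own mRNA is cut by Drosha, had -2.34 in the authors' deposited table. The CNOT1 peak had a log average of -6.56, too low for the rule used for the largest log ratios. Oxidative and metal stress genes had a median of 1.31, with 12 of 15 above 0 (percentile 70.465), and GCLM, a glutathione synthesis subunit, had 2.69. With all peaks of a gene, the oxidative, ribosomal and microRNA machinery lists lay above the range as well, so that 4 lists did, although ranges over several peaks of a gene are too narrow. With the median over each gene's peaks, the ribosomal list was the only one outside, at 1.43 against a range of 0.62 to 1.22 (percentile 99.99).

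With 1 peak per gene, the stress response lists did not stand apart. The share of all genes above 0 was 79.9%, so most members being above 0 does not set a list apart. Above the median of all genes, 1.10, lay 7 of 19 heat shock, 9 of 25 immediate early and 11 of 27 integrated stress response genes. For stress granule and cell cycle genes these counts were 17 of 29 and 19 of 37. Heat shock and chaperone mRNAs had a median of 0.48, below the matched lists by 0.64 but inside their range (percentile 3.655), with 15 of 19 genes above 0. CHORDC1, an Hsp90 co-chaperone, and CACYBP had 3.02 and 2.90, and HSPH1, a large Hsp70-type chaperone, had -1.14 in the authors' deposited table. The direction of this list turned with all peaks, where it lay at percentile 66.06. Immediate early genes had a median of 0.86 with 19 of 25 genes above 0, among them MCL1, a survival factor, with 1.71. In the integrated stress response list the median was 0.92, with 21 of 27 genes above 0. EIF2AK3 and EIF2S1, the PERK kinase and its eIF2 alpha substrate, had 4.45 and 3.20, while ATF4, the transcription factor of this response, had -0.45 in the authors' deposited table. Stress granule and RNA-binding genes had a median of 1.31 with 24 of 29 above 0, and G3BP1, a granule core protein, had 1.97. Cell cycle genes had a median of 1.15 with 31 of 37 above 0, and MKI67, a proliferation marker, had 3.10. The MKI67 peak had a log average of -7.07, too low for the rule used for the largest log ratios. No mitochondrially encoded gene was listed, and of the markers of other cell types only the neuronal NEFL was, with 2.43.

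The second comparison asked whether the miRNAs bound to Ago2 differed between treatments. No miRNA did by the authors' test. In the authors' deposited table, made with DESeq, 0 of 1213 entries had an adjusted p under 0.05 and every adjusted p was 1. An unadjusted p under 0.05 was listed for 24 entries in the authors' deposited table, where 60.65 would be met by chance if p-values were spread evenly. Only 624 of the entries had a mean of at least 20. The lack of a passing entry does not show that the miRNAs were unchanged. The miR-30 family held 24.3% of the summed means of the mature miRNAs, miR-196 14.3%, miR-19 8.99% and miR-15/16 6.09%, from the authors' deposited table. The most abundant miRNA, miR-196b-5p, had authors' means of 2333840 untreated and 2301170 with arsenite in the authors' deposited table (log2 fold change -0.02). miR-30e-5p had a log2 fold change of -0.18, miR-30a-5p -0.15, miR-30d-5p -0.18, miR-16-5p 0.02, miR-19b-3p -0.13, miR-374a-5p 0.20, miR-19a-3p -0.14 and miR-27a-3p -0.07 in the authors' deposited table. miR-31-5p had the largest difference of these 10, with a log2 fold change of -0.46 (p = 0.0483, adjusted p = 1 by DESeq in the authors' deposited table). These 10 miRNAs held 63.3% of the mature sum.

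Few miRNA families stood apart as groups. Of 29 families and classes fixed before the data were examined, 23 had at least 2 members with a mean of 20 or more, and 1 lay outside the range of matched lists, where 1.15 would by chance. That list, miR-320 and other hairpins that bypass Drosha or Dicer, had a median log2 fold change of 0.27 over 10 members, 8 of them above 0, from the authors' deposited table. The log2 ratio of its summed means was only 0.03, so the total amount of these miRNAs hardly differed. The let-7 list had a median of 0.17 with 8 of 9 members above 0, the miR-17 list -0.03, miR-19 -0.13, miR-25/92 0.06 and miR-30 -0.15. The 9 members of the oxidative stress and hypoxia list had a median of -0.11, and the 143 passenger strands described had a median of 0.03. The serum and other-cell-type list had a median of -0.02 over 11 members. All of these lay inside their ranges.

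The third comparison asked whether families whose miRNA was more abundant on Ago2 after arsenite had higher log ratios at their peaks. Over the 49 families with at least 20 peaks, Pearson's r between the miRNA log2 fold change and the median log ratio was 0.51 (permutation p = 0.00021, adjusted p = 0.000892 over 17 relations computed), and Spearman's rho was 0.43 (permutation p = 0.00277, adjusted p = 0.0133). Without the 2 families farthest from the median fold change r was 0.42. Families are not independent replicates, since peaks can match several of them. The miR-324-3p, miR-18a-3p, miR-449a and miR-708-5p families lay at the low end of both measures, with miRNA log2 fold changes of -0.60, -0.57, -0.54 and -0.49. The miR-210 family, with a median as low, had -0.03. Among the 17 families over 1% of the LO band sum r was 0.64 (permutation p = 0.00689), but rho was 0.26 (permutation p = 0.303) and r was 0.0539 without 2 families, so that relation rests on those 2. In the 21 families whose site was fixed before the data were examined r was 0.26 (permutation p = 0.259), and it was -0.01 without 2 families. The miRNA log2 fold changes of these 21 ran only from -0.28 to 0.34, so they leave out the low end of the relation. With the families' median peak length removed from both measures, r over 49 families was 0.28 (permutation p = 0.0518, adjusted p = 0.0880) and rho was 0.30 (permutation p = 0.0351, adjusted p = 0.0854).

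**Figure D3:**
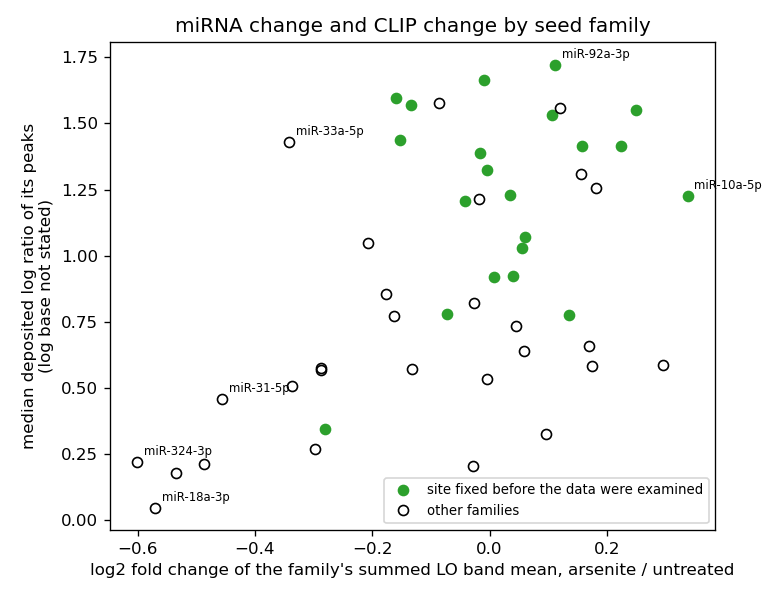
Each of 49 points is a seed family, with the log2 fold change of its summed LO band means (horizontal axis) against the median deposited log ratio of its CLIP peaks (vertical axis, log base not stated), filled where the site was fixed before the data were examined. The 4 families of the lowest log2 fold changes, from -0.60 to -0.49, have medians from 0.05 to 0.22 and are not among the filled points. The 21 filled points have r = 0.26.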

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

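No paired analysis was possible because the deposited tables hold no values of single replicates. For the same reason the planned replicate blocks, other normalizations, DESeq2 and limma-voom fits, left-out replicates, library-size changes, camera and fry variants and interaction tests were not run, and other seed lengths or extended peaks were not run since no hg19 sequence was used here. The settings using 1 peak per gene, non-overlapping or longer peaks, left-out transcripts, length or region matching, a gene's median peak, and subsets or corrections of the family relation, other than families over 1%, were chosen after seeing the data. The region differences and the seed difference over all regions kept their sign and stayed outside the random range under each setting run. Against matched sets, which hold peaks with and without a match, the seed difference lay between 0.33 and 0.42. The 0.25 within gene and region sets peaks with a match against peaks with none, so its size cannot be compared with these. Within single regions the seed difference did not always stay outside the range. In 5'UTRs it was -0.01 within genes, and in noncoding exons 0.21 within genes and 0.10 with sets matched on average, all inside the range. The noncoding difference shrank from -0.74 to -0.35 with 1 peak per gene and to -0.45 without XIST, MALAT1, KCNQ1OT1 and NEAT1, where the noncoding medians were above 0, and the 5'UTR difference grew from -0.41 to -0.84 with 1 peak per gene. The share of peaks above 0 was 79.9% with 1 peak per gene, 71.6% with non-overlapping peaks and 71.3% without XIST, MALAT1, KCNQ1OT1 and NEAT1. Families above the range numbered 14 with 1 peak per gene, where fewer peaks enter. The family correlation of 0.51 stayed past the threshold with medians minus fully matched sets (0.51) and without 3 families of a minor arm (0.45, but rho 0.35 with adjusted p = 0.0575). It was 0.26 over the 21 families with a fixed site and 0.33 in these same 21 with site GC removed. GC removal did not lower it there, but none of the 6 families below the range is among these 21. Over 49 families the correlation was 0.28 with peak length removed. These 3 correlations were not past the threshold (with length removed, rho was 0.30 with permutation p = 0.0351 before adjustment). Lists outside the range numbered 4 with all peaks of a gene and 1, the ribosomal list, with a gene's median peak. Differences from matched lists changed sign with all peaks for heat shock (0.0676), integrated stress response (0.0796) and stress granule genes (-0.13), and for cell cycle genes with the median peak (-0.19) and with the filter on low averages (-0.0828), where the main differences were -0.64, -0.17, 0.17 and 0.05. The cause was not tested for these. No miRNA entry passed at a threshold of 0.01 or with a minimum mean of 20 (624 entries, smallest recomputed Benjamini-Hochberg value 1), and 1 miRNA list lay outside at each pseudocount tried. Unknown depth limits what can be said of any single peak.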

Other observations

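The tests in this part were chosen after the result was seen, except the removal of peak length from the family relation, which was fixed before its result was seen, and the planned family relation itself.

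Small nucleolar RNAs, which guide modification of ribosomal RNA, carried some of the highest log ratios. The 105 peaks in 89 of these genes had a median of 2.26, and 102 lay above 0. Box C/D members (SNORD genes) had a median of 2.45 over 66 peaks and box H/ACA members (SNORA genes) 1.54 over 39. SNORD41 had 4.88 and SNORD99 4.26 in the authors' deposited table, and SNORD111B was low at -1.47. The first 2 peaks had log averages of -7.25 and -7.18, too low for the rule used for the largest log ratios. Exons of 10 genes that host small nucleolar RNAs had a median of 0.83 over 31 peaks, inside the range of matched sets. Other small RNAs were mixed: RPPH1, the RNA of RNase P, had a median of 2.58 and the spliceosomal RNU12 3.19, while SCARNA2, a Cajal body RNA, had -1.09 over 9 peaks. MALAT1, a nuclear speckle RNA, had only 3 of 105 peaks above 0 and a median of -0.81. KCNQ1OT1, an imprinted antisense RNA, had a median of -0.38, and NEAT1, the paraspeckle RNA, -0.06. The 182 peaks on lincRNA models had a median of -0.22.

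The high log ratios of small nucleolar RNA peaks are not explained by their average values or lengths, since their median lay 1.67 above sets matched on both. A change in the RNA level of these short transcripts or in its measurement stays open, because the normalizer is not stated and RNA-seq values were not analysed here. The low values in noncoding exons did not come from 4 long nuclear RNAs alone. Without these 4 the difference from sets matched on average was -0.45 in place of -0.74, still outside the range, with the high small RNA peaks left in. Without these 4 and without small RNAs, the other 638 noncoding peaks in 211 genes had a median of -0.11. Their difference from sets matched on average and length was -0.71, against -0.70 for all noncoding peaks on the same matching.

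Peaks with a seed match had higher log ratios than other peaks. Peak length, average and region do not account for it, since the difference from sets matched on all of these was 0.34. A change of the whole transcript, or its scaling, does not account for all of it either, since the median difference within the same gene and region was 0.25. Over all peaks the medians with and without a match were 1.06 and 0.48, which lie farther apart, though over a different set of genes. Base composition of the sites stays open. Over 21 families with a fixed site, the share of G and C had r = -0.23 with the matched difference (permutation p = 0.316). None of the 6 families below the random range had a fixed site. The 21 families therefore cannot show whether site composition goes with the low medians.

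Families differed in the median log ratio of their peaks, and a shift in the amount of each miRNA on Ago2 is a candidate explanation. The relation over all 49 families (r = 0.51) was not seen past the threshold in the 21 families with a fixed site (r = 0.26). The fold changes of those 21 ran only from -0.28 to 0.34, so they cannot decide whether the relation holds at the low end. No miRNA passed the authors' own test. Peak length is another candidate explanation. Families with shorter peaks had higher medians (r = -0.80 over 49 families, permutation p = 1e-05, the smallest that the permutations can give). With length removed the relation with miRNA fold change was r = 0.28 (permutation p = 0.0518) and rho = 0.30 (permutation p = 0.0351, adjusted p = 0.0854). With medians minus sets matched on average, length and region the relation was r = 0.51 (permutation p = 0.00016, adjusted p = 0.000892), but these differences still went with the families' median length (r = -0.71). With that length removed as well it was r = 0.30 (permutation p = 0.0373, adjusted p = 0.0704) and rho = 0.31 (permutation p = 0.0344, adjusted p = 0.0854). These explanations cannot be told apart here. miRNA abundance also went with the medians (r = 0.36, permutation p = 0.0106, adjusted p = 0.0257), but Spearman's rho was 0.29 (adjusted p = 0.0861).

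Several of the largest log ratios lay in mRNAs of endoplasmic reticulum or membrane proteins, which prompted a test of secretory pathway mRNAs as a group. A list of such genes was written after that and first looked at with RPN2, and without RPN2 it had 27 measured members and a median of 1.22, which was 0.0797 above matched lists and inside their range of 0.57 to 1.71. The hypothesis that these mRNAs moved together was not borne out at this size of list, and a smaller shift cannot be ruled out.

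Genes sharing a symbol prefix were also looked through without a planned test, and nothing is reported from them. By chromosome, the median log ratio ran from 0.26 on chromosome 22 to 1.16 on chromosome 18. The 208 genes with 17 or more peaks had a median of 0.57 at their highest-average peak, against 1.10 for the 2339 genes with 1 peak. Among the 213 stem and loop entries of the miRNA table, an entry labelled only as loop had means of 635.8 untreated and 474.1 with arsenite (p = 0.153 in the authors' deposited table). The smallest p in that table belonged to miR-197-3p, with a log2 fold change of 0.79 (p = 0.00258, adjusted p = 1 by DESeq in the authors' deposited table).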
